A study of Arabidopsis thaliana with 2 samples.

How the data were processed

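H3K27me3 was measured by chromatin immunoprecipitation and sequencing in whole Arabidopsis thaliana seedlings of 10 days, in 1 wild-type and 1 ref6-1 library. Per the labels' protocols, seedlings grew on plates at 23 °C with 16 h of light and 8 h of dark, nuclei were sonicated, and the DNA was ligated to adapters, selected on a gel at 300 bp and amplified for 18 PCR cycles. No input library was used here, so background was estimated within each library.

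The authors deposited 1 row per aligned read of 36 bases, and per the file headers and the submitters' processing notes the reads were aligned to TAIR9. The files carry the layout of ELAND export rows, per the read me of the series. The version of the aligner and its filters are not given in the sources used here. The deposited rows give the position and strand of each read, the match to the reference and an alignment score, which the aligner assigned and which was used here only in 1 alternative. The signal tracks that the read me describes were not used here. Each library came from 1 sequencing lane, with 120 tiles in wild type and 119 in ref6-1. The files held 6227500 wild-type and 5424383 ref6-1 aligned reads, of which 3.26% and 2.29% lay on the chloroplast and 0.479% and 0.339% on the mitochondrial genome. Among aligned reads 94.0% and 93.4% had no mismatch.

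The planned tests assumed reads per gene, and the files hold read positions, so reads were counted here. One read was kept per position and strand among nuclear reads, leaving 2928881 and 1688610 reads. Each 5′ end was moved 100 bp downstream, near the middle of the fragment, where the offset between strands gave a fragment estimate of 175 bp in both libraries. Reads were counted from gene start to gene end. Background was the median 1 kb bin, 14 reads in wild type and 7 in ref6-1, or 4.78 and 4.15 RPM (reads scaled to library size). A protein-coding gene was called marked when its density averaged over both libraries was at least 2 times background with at least 20 reads summed.

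Genes came from a table of assembly TAIR10.1, which pairs locus tags with symbols. Of the 237 list entries, 236 distinct genes, all locus tags were found, and 231 symbols matched. The table was made for another assembly name than that of the reads, so its coordinates are not printed, and they were used only to assign reads to genes. The shared frame was checked with the internal promoter motif of tRNA genes in sequence rebuilt from mismatch-free reads. Of 112 motif hits within 500 bp of the 625 tRNA genes, 62 lay at exactly 22 bp from a gene end, and the next most frequent distance had 5. On each chromosome 10 to 14 hits lay at that distance, spanning at least 89.9% of its length. The table holds no strand, so gene profiles fold both ends together and overlapping genes share reads.

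The ratio of ref6-1 to wild type used RPM over distinct nuclear reads, with an exact conditional binomial (Clopper-Pearson) 95% interval for counting error. The median interval spanned 1.90-fold from bound to bound. A pseudocount of 0.5 reads entered log2 values only. A gene was called higher at a ratio of at least 1.5 with a lower bound above 1, and lower in the mirror case. No p-value is given, since genes are not replicates and there was 1 library per genotype. A gene at 0 reads was given a fold against a floor of 3 counts. Regions were called on both libraries pooled after wild type was thinned to the ref6-1 depth, from 200 bp bins with a Poisson upper tail under 0.001 (at least 11 reads against 3 expected), with gaps up to 400 bp joined and a minimum of 600 bp.

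The 19 gene lists (floral organ identity, flowering time, shoot meristem KNOX and WOX, organ boundary and YABBY, embryo and seed maturation, endosperm and imprinted, gibberellin, auxin, cytokinin, abscisic acid and brassinosteroid genes, leaf senescence, trichome and stomata, root patterning, anthocyanin and proanthocyanidin, triterpene clusters, heat shock, Polycomb and demethylases, constitutively active) were fixed before the data were examined. A list median was placed among 10000 random lists of the same size drawn from marked genes in 10 bins of density, as a description of these libraries. The rule for named genes took, among marked genes with at least 50 reads, the 15 with the highest lower bound and the 8 with the lowest upper bound, up to 4 marked members per list with the largest log2 ratio in size, and always REF6, ELF6, FLC, FT, SOC1, AG, STM and the constitutively active list. A named gene that overlaps another annotated gene is given with that fact.

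The gene comparison was tested on simulated Poisson counts for the 27432 genes with 200 changed genes. Of genes raised by 2-fold 31 of 33 were recovered, by 3-fold 33 of 33 and by 1.5-fold, the threshold itself, 19 of 34. Of genes lowered by 2-fold 25 of 33 were recovered, by 3-fold 23 of 33 and by 1.5-fold 15 of 34. A call also needs the level for a mark, and how many lowered genes fell under it is not given here. Among 8687 simulated marked genes without a change, 126 (1.45%) were called. Of 100 simulated lists without a shift, 3 lay outside the middle 95% of random lists.

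Alternatives covered 3 other scalings, all reads kept, no shift of the 5′ end, each strand, mismatch-free reads, lower and upper tiles, thinning of wild type, other levels for a mark, other minimum read numbers, a ratio of 2 and other region settings. Gene bodies with 1 kb on both sides, an alignment score of at least 100, the removal of a GC trend and the settings of the motif search were added after seeing the data. So were list medians over all members with reads, marked or not, placed among 10000 random lists matched on wild-type density, ratios beside genes without another gene near, and a removal of the trend with wild-type density, the median log2 ratio in 100 classes of density, where a random part of the wild-type reads gave the density and the other part the ratio. The planned 1 kb upstream of genes and the profile along the direction of the gene need strand and were not run. Calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.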

Results

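The study compared trimethylation of lysine 27 on histone H3 (H3K27me3) between Arabidopsis thaliana wild type of the Columbia accession and the ref6-1 mutant. H3K27me3 is the mark that Polycomb repressive complexes place on silenced genes, and REF6 (RELATIVE OF EARLY FLOWERING 6) is a JmjC-domain demethylase of this mark. Whole seedlings were harvested at 10 days, and chromatin was immunoprecipitated with an H3K27me3 antibody and sequenced. There was 1 library per genotype, so no difference below has a replicate check, and every comparison is between these libraries, not between the conditions. The wild-type file held 6227500 aligned reads and the ref6-1 file 5424383. After reads of the organelles were set aside and 1 read was kept per position and strand, 2928881 wild-type and 1688610 ref6-1 reads remained, because 51.1% of the wild-type and 68.0% of the ref6-1 nuclear reads repeated a position. All intervals are exact 95% intervals that cover counting error only, since PCR reads without molecular identifiers are not independent molecules.

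More genes and regions passed the level for H3K27me3 in ref6-1 than in wild type, with the level set by each library's own background. Of 27432 protein-coding genes, 8828 (32.2%) had a mean read density of at least 2 times background over both libraries and are called marked here. In wild type alone 7749 genes passed that level, and in ref6-1 alone 9269. The share of reads that fell in H3K27me3 regions was 54.3% in wild type (Clopper-Pearson 95% interval 54.29 to 54.40) and 59.3% in ref6-1 (59.27 to 59.42). Regions called in each library at equal depth numbered 6317 in wild type, covering 11.2 Mb at a mean of 69.2 reads per kb, and 7474 in ref6-1, covering 15.3 Mb at a mean of 62.8 reads per kb. Background was 4.78 RPM per kb in wild type and 4.15 in ref6-1, so the ref6-1 cutoff for genes was lower in RPM. The regions of each library were also called against its own background. How much of the excess in ref6-1 follows from these cutoffs was not tested. The targeted gene itself carried no mark in either library. REF6 (AT3G48430) had 90 wild-type and 36 ref6-1 reads, 1.16 and 0.929 times background, with a ratio of 0.694 (0.458 to 1.03). Reads of immunoprecipitated DNA over the gene do not check whether it is inactivated, so the labels were taken as given. Its relative ELF6 (AT5G04240) was also unmarked, with a ratio of 0.787 (0.524 to 1.16), and shared reads with the overlapping gene AT5G04238.

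Genes with more H3K27me3 in ref6-1 outnumbered those with less. Among the 8828 marked genes, 1957 (22.2%) were higher in ref6-1, 644 (7.29%) were lower, and 6227 were neither. Higher means a ratio of at least 1.5 with the lower bound of its interval above 1, and lower is the mirror of this. The median fold of the higher genes was 2.45. Of them 1333 reached 2-fold and 393 reached 4-fold, against 172 genes at least 2-fold lower. Their median density went from 1.97 times background in wild type to 6.55 times in ref6-1. Genes called neither had 6.15 times in wild type and 6.78 times in ref6-1. These values are in times each library's own background, which was lower in ref6-1 in RPM, so they rise more than the ratios do. In wild type, 1000 of the 1957 higher genes (51.1%) lay under the level for a mark. Genes with a mean density 2 to 3 times background were higher in 30.8% of cases and those above 8 times in 8.24%. Lower calls also became rarer with density, 9.35% and 3.77% in these classes. Every chromosome held higher genes, from 18.5% of the marked genes on chromosome 2 to 24.7% on chromosome 4. The median log2 ratio over all marked genes was 0.03 (quartiles −0.27 and 0.53).

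The split depended on how the libraries were scaled. The higher genes made up 75.2% of the calls when scaled to distinct nuclear reads, 72.4% (1906 higher, 725 lower) with the median ratio of marked genes set to 1, 87.2% (2336 and 342) with a trimmed mean, and 97.0% (3217 and 99) when scaled to background bins. These scalings moved the median of all marked genes by −0.03, 0.16 and 0.40 on the log2 scale, so ratios near 1 are relative to that choice. Background bins are the 1 kb bins at or below the background median in both libraries, with their reads summed. Their factor is therefore not the ratio of the medians behind the values in times background. The median log2 ratio of the 15871 unmarked genes with at least 20 reads was −0.26 under the main scaling. It was −0.29 with the marked median set to 1, −0.10 with the trimmed mean and 0.14 with background bins. So no scaling put unmarked genes at a ratio of 1, and background scaling alone put them above it.

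**Figure D1:**
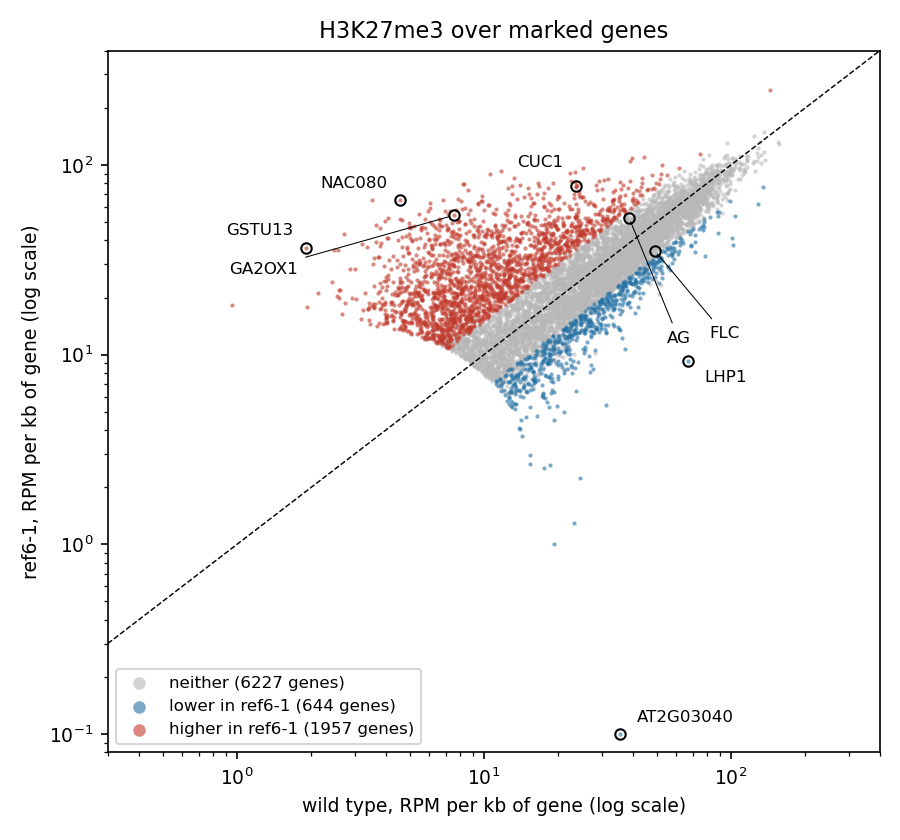
Read density of each of the 8828 marked genes in wild type (x axis) and ref6-1 (y axis), both in reads per kb of gene after scaling to library size (RPM per kb), on log scales, with the line of equal density dashed. Of the 1957 genes higher in ref6-1 (red) 957 were marked in wild type already, the 644 lower genes (blue) lie below the line, and AT2G03040, with 0 ref6-1 reads, is drawn at 0.1 near the lower edge.

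The genes with the firmest gain were of several kinds, most of them near background in wild type. GSTU13 (AT1G27130), a glutathione S-transferase, had 9 reads in wild type and 100 in ref6-1, a ratio of 19.3 (9.76 to 43.4), and GSTF6 (AT1G02930), of the same enzyme class, a ratio of 15.9 (8.53 to 32.9). The NAC-domain transcription factors NAC080 (AT5G07680) and NAC004 (AT1G02230) had ratios of 14.2 (9.37 to 22.5) and 13.1 (8.30 to 21.8). The heat shock transcription factor HSFA7A (AT3G51910) stood at 14.5 (7.92 to 28.9), the formin FH8 (AT1G70140) at 10.4 (7.67 to 14.4), the receptor-like protein RLP29 (AT2G42800) at 10.2 (6.78 to 15.8) and the sieve element protein SEOa (AT3G01670) at 9.84 (7.42 to 13.2). BST1 (AT5G65090), needed for root hair growth, had a ratio of 11.8 (7.93 to 18.3) and overlaps AT5G65100. The unnamed loci AT3G21330, AT4G35070, AT1G75060, AT5G37440, AT3G05320 and AT5G56810 complete the 15 genes with the highest lower bounds, with ratios from 18.6 (11.8 to 31.1) for AT3G21330 to 9.66 (6.93 to 13.8) for AT5G56810. AT3G05320 overlaps MIRO3.

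Among the lower genes, those with the lowest upper bounds were LHP1, AT5G24240 with 44 ref6-1 reads, and loci with at most 13 ref6-1 reads. LHP1 (AT5G17690), the chromodomain protein that binds H3K27me3, had 513 wild-type and 41 ref6-1 reads, which is 7.21-fold lower in ref6-1 (5.24 to 10.2). Its wild-type reads lay in 3 separate blocks with flanks of 0.929 and 1.36 times background, and it overlaps AT5G17680. AT2G03040 had 96 wild-type reads and 0 ref6-1 reads, within an interval of 9.70 kb that held 0 ref6-1 reads. This is 18.4-fold lower with its count set to the floor of 3, and at least 14.7-fold lower at the 95% bound. The other 6 genes with the lowest upper bounds were AT5G05060 (ratio 0.173, 0.0899 to 0.307), AT5G21050, AT1G12672, AT3G53550, AT2G05330 and AT5G24240 (0.300, 0.213 to 0.415). AT5G24240 overlaps AT5G24230. AT2G03040, AT5G21050 and AT3G53550 lost their call under 3 alternative settings, and AT1G12672 and AT2G05330 under 2.

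Among the gene lists, chosen before the data were examined, those of gibberellin, auxin and abscisic acid genes had median log2 ratios near 0 (−0.13, −0.01 and 0.05), within the middle 95% of random lists, with single members higher. Of 14 gibberellin metabolism genes, all marked, 5 were higher in ref6-1. These were the gibberellin-inactivating oxidases GA2OX1 (7.19-fold, 4.92 to 10.8), GA2OX3 (4.69, 2.98 to 7.59) and GA2OX2 (2.81, 2.07 to 3.83), the synthesis gene GA20OX2 (4.64, 3.59 to 6.04) and, named outside the rule, GA20OX1 (2.47, 1.83 to 3.34). Of 16 marked genes of auxin synthesis and transport, 4 were higher, namely YUC3 (8.16, 5.69 to 11.97), YUC7 (2.03, 1.20 to 3.46), YUC8 (1.74, 1.41 to 2.16) and the efflux carrier PIN7 (1.92, 1.36 to 2.71). YUC7 overlaps AT2G33220 and lost its call under 8 of 19 alternative settings, PIN7 under 4, and YUC8 and GA2OX3 under 1 each. Of 8 marked abscisic acid genes, 3 were higher: the catabolic hydroxylase CYP707A1 (4.11, 2.97 to 5.76) and the synthesis genes NCED9 (2.02, 1.48 to 2.75) and NCED3 (1.59, 1.11 to 2.26), the last losing its call under 8 settings. CYP707A2 was lower at 0.644 (0.490 to 0.839) and lost its call under 7 settings, background and trimmed-mean scaling among them. The unmarked CYP707A3, named outside the rule, had a ratio of 4.37 (2.66 to 7.43).

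Brassinosteroid genes were the only list whose median lay above the middle 95% of 10000 random lists matched on density, among 18 lists with marked members, though marking uses both libraries and so favours changed genes. Of its 4 marked members 3 were higher: XTH22 (5.61, 3.79 to 8.51), a cell wall enzyme, and the synthesis enzymes DWF4 (5.16, 3.56 to 7.62) and BR6OX1 (2.98, 2.25 to 3.96). DWF4 lost its call under 2 settings. ROT3, which overlaps AT4G36370, had a ratio of 0.820 (0.660 to 1.01). The median of the 4 marked genes was 1.96 on the log2 scale, above 99.6% of the random lists. With the unmarked CPD (−0.35) and BR6OX2 (0.15), named outside the rule, the median of all 6 members was 0.86, above 99.3% of random lists matched on wild-type density, a comparison chosen after seeing the data. With 18 lists compared, 1 list past the middle 95% can also arise without a shift. Of 100 simulated lists of 12 genes without a shift, 3 lay outside that range. None of the 11 marked cytokinin metabolism genes was higher or lower, with log2 ratios from −0.55 (IPT1) to 0.25 (IPT4), although 1 was higher under background scaling.

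Genes of senescence, heat response and organ boundaries also held single higher members. In the leaf senescence list 3 of 5 marked genes were higher, the stay-green gene NYE2 (3.27, 2.43 to 4.44) and the NAC factors NAC092 (2.31, 1.55 to 3.48) and NAP (2.20, 1.40 to 3.49), and the median of the marked genes, 1.14, lay above 96.2% of random lists. The median of all 11 members was 0.45, above 99.4% of random lists matched on wild-type density, and the 6 unmarked ones ranged from −1.23 (WRKY53, named outside the rule) to 0.79. In the heat shock list 2 of 4 marked genes were higher, the small heat shock proteins HSP21 (3.56, 2.41 to 5.33) and HSP22 (2.23, 1.32 to 3.79), and HSP22 and NAP lost their call under 2 settings. The unmarked HSP18.2 (0.278, 0.0702 to 0.804) and HSP101 (0.415, 0.229 to 0.713), named outside the rule, had lower ratios. Of 15 marked boundary and YABBY genes 2 were higher, the NAC factors CUC1 (3.30, 2.65 to 4.13) and CUC3 (1.95, 1.501 to 2.53), which set organ boundaries. CUC3 lost its call at a ratio threshold of 2. Of 18 marked embryo and seed maturation genes only AGL15 (2.77, 2.16 to 3.56) was higher under the main scaling. The proanthocyanidin enzyme gene BAN (2.35, 1.57 to 3.54) was higher among 8 anthocyanin and proanthocyanidin genes, where the MYB factor PAP1 was lower (0.596, 0.391 to 0.888). The trichome factor GL1 (0.647, 0.493 to 0.843) was the 1 lower gene of 9 marked trichome and stomata genes. PAP1 and GL1 each lost the call under 5 settings, background scaling among them, and BAN under 1.

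The floral and meristem regulators, with 8.35 and 8.98 times background at the median in wild type, gave no calls. Higher calls were rare at such densities in general. Of all 2407 marked genes above 8 times background in wild type, 34 (1.41%) were higher and 151 lower. Wild-type reads set both this class and the ratio, so the share of higher calls is low in part by construction. By mean density over both libraries, 223 of 2705 genes above 8 times background (8.24%) were higher and 102 lower. None of 14 floral organ identity genes was higher or lower, from −0.27 (SEP4) to 0.44 (AG) on the log2 scale, although background scaling put 3 of them past the threshold. AG had 644 wild-type and 504 ref6-1 reads, a ratio of 1.36 (1.21 to 1.53). None of 17 KNOX and WOX genes passed under any of the 4 scalings, and STM had a ratio of 1.12 (0.987 to 1.27). Among 12 marked flowering time genes, only MAF4 (1.83, 1.52 to 2.20) was higher under the main scaling, and it lost the call at a ratio threshold of 2. FLC, the repressor of flowering, had a ratio of 0.719 (0.635 to 0.814), which is not past the threshold, and overlaps the noncoding gene AT5G01675. The ratios of FT and SOC1, which promote flowering, were 0.967 (0.771 to 1.21) and 0.777 (0.607 to 0.989). No marked member passed under the main scaling among 6 endosperm and imprinted genes, 7 root patterning genes and 6 genes of triterpene clusters. Of the Polycomb and demethylase list 3 of 17 genes were marked, and LHP1 was the 1 call, with MEA at 1.04 (0.903 to 1.21). None of the 14 constitutively active genes was marked, and their median log2 ratio was −0.24, beside −0.26 for the 15871 unmarked genes with at least 20 reads, and became 0.16 under background scaling. Over all lists, 25 of 176 marked members (14.2%) were higher, against 22.2% of all marked genes, and 4 were lower. These shares were not matched on wild-type density. In 14 of the 19 lists the median lay below 0, and under background scaling all 14 were above 0.

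**Figure D2:**
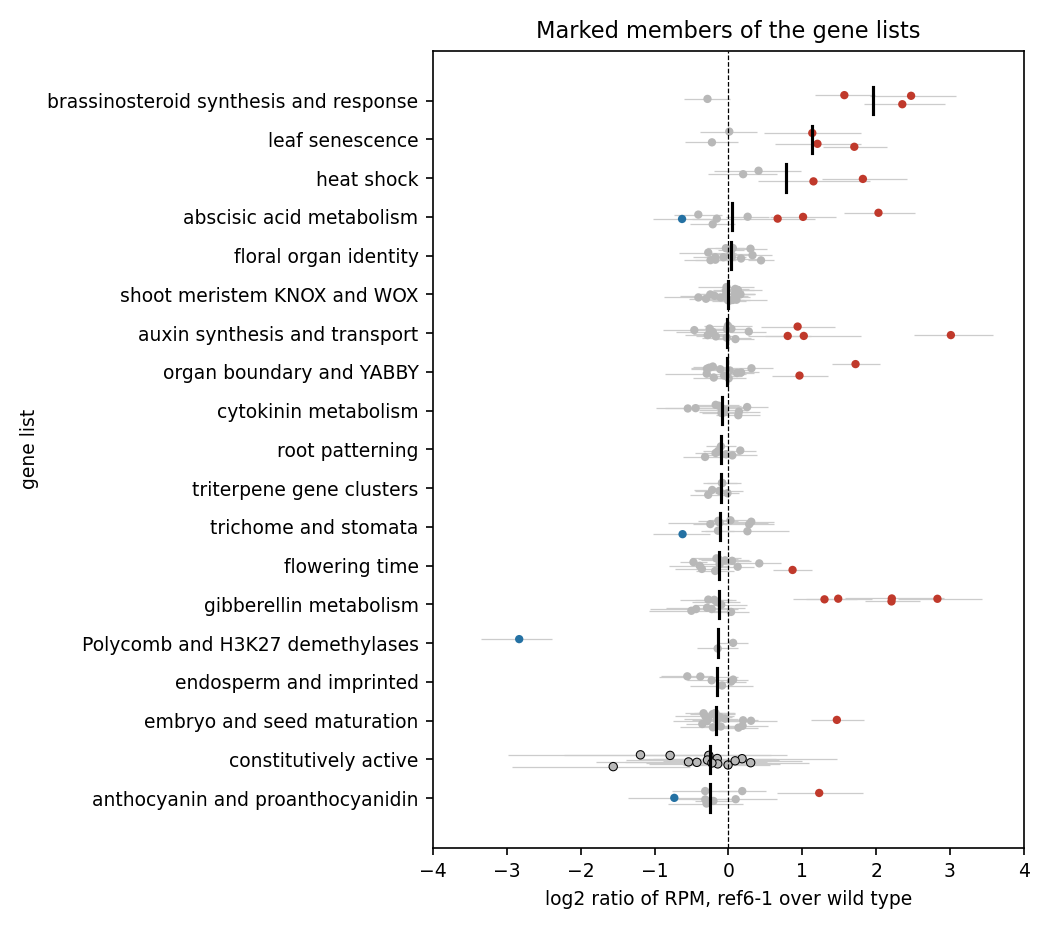
Log2 ratio of RPM (ref6-1 over wild type, x axis) of each marked member of the 19 gene lists (y axis), with the exact 95% interval as a grey line and the list median as a black bar; red and blue points are genes called higher and lower, grey points neither. The constitutively active genes, none of them marked, are outlined in black, and the brassinosteroid list has the highest median, 1.96.

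H3K27me3 regions, called without the annotation, gave the same balance. Of 7767 regions (17.4 Mb, median length 1600 bp), 1552 were higher in ref6-1, covering 2.94 Mb, and 490 were lower, covering 0.625 Mb. Of the higher regions 1438 (92.7%) overlapped a protein-coding gene, and 1112 overlapped no region called in wild type at equal depth. In TAIR9 coordinates, the firmest gains among regions of at least 1 kb lay over GSTU13 (chromosome 1, 9425400 to 9426799, ratio 21.2, 10.4 to 50.6), NAC080 (chromosome 5, 2435800 to 2437399, ratio 14.8, 9.57 to 23.9), FH8 (chromosome 1, 26412600 to 26414999, ratio 10.7, 7.85 to 15.01), AT4G35070 (chromosome 4, 16694200 to 16695599, ratio 12.4, 7.74 to 20.9), AT3G05320 (chromosome 3, 1514000 to 1515599, ratio 11.97, 7.46 to 20.2) and NAC004 (chromosome 1, 435200 to 437599, ratio 10.9, 7.41 to 16.6). The region of that length with the lowest upper bound lay over LHP1 (chromosome 5, 5827600 to 5829599, ratio 0.136, 0.0956 to 0.189), where the blocks and the gap of the wild-type reads leave it in doubt whether they are H3K27me3. The shorter region over AT2G03040 had 81 wild-type and 0 ref6-1 reads. The region over GA2OX1 spanned 29511800 to 29513199 of chromosome 1 and that over CUC1 5109600 to 5111599 of chromosome 3. Under background scaling 2705 regions were higher and 74 lower, and with all aligned reads kept 2830 and 1268.

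**Figure D3:**
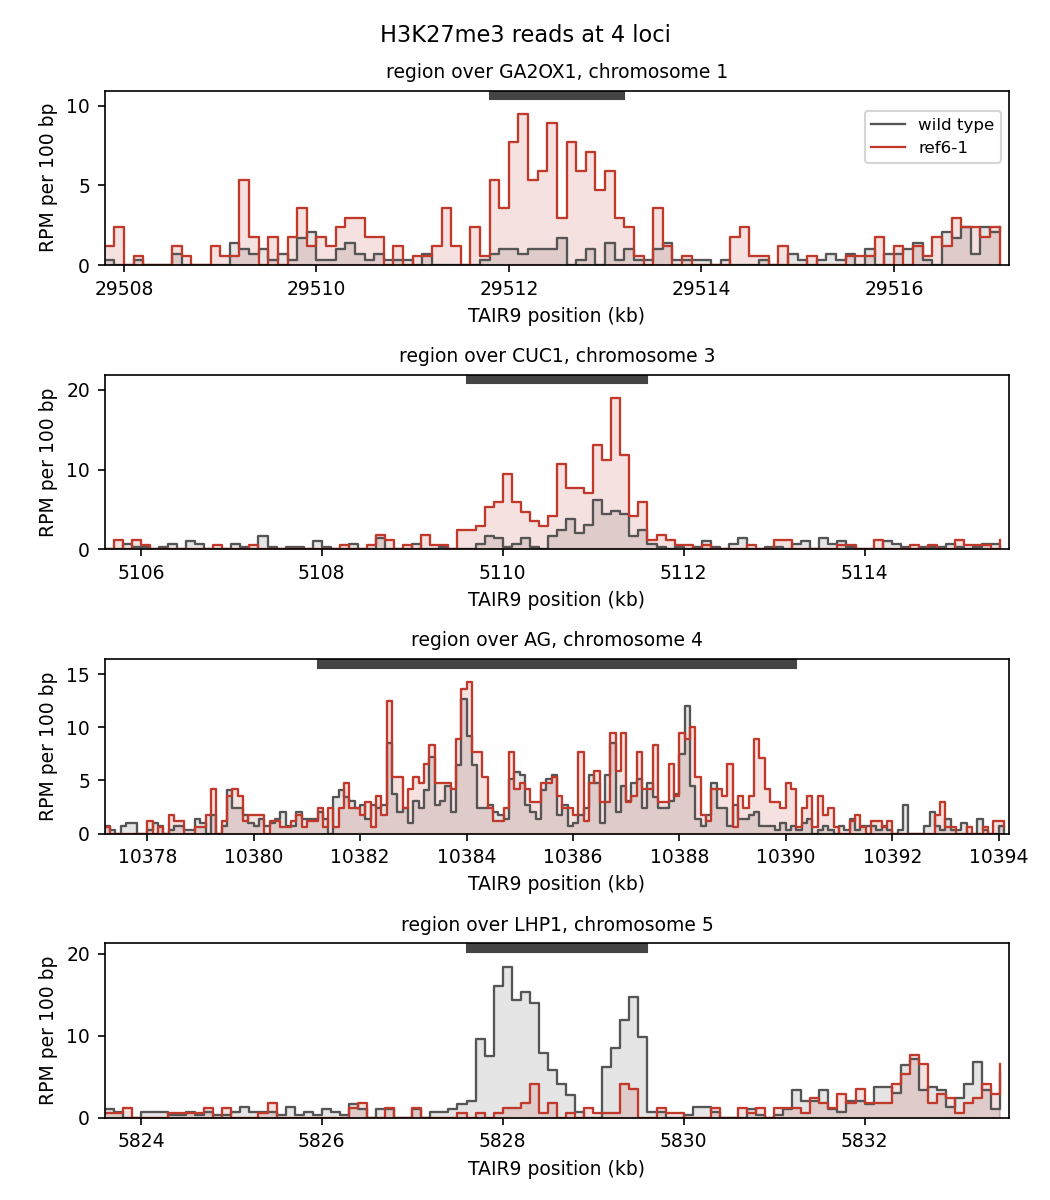
Distinct reads, scaled to library size (RPM), in bins of 100 bp (y axis) along TAIR9 positions in kb (x axis) around the regions over GA2OX1, CUC1, AG and LHP1, wild type in grey and ref6-1 in red, with the called region as a dark bar at the top. Reads over GA2OX1 and CUC1 are higher in ref6-1 along the region, AG is covered in both libraries, and the wild-type reads over LHP1 leave a gap inside the region.

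In the higher genes the difference also reached the DNA beside the gene. Genes were called from reads inside the gene, so the values there follow from the calls. Among the higher genes of at least 1 kb, 1686 in number, the ratio of mean densities was 2.02 just outside the gene ends and 1.55 at 1 kb outside, beside 2.69 in the middle of the gene. Lower genes (476) had 0.579 in the middle, and 0.872 just outside and 0.822 at 1 kb outside. These outside values lay near the log2 median of −0.26 of unmarked genes and below those of genes called neither. Genes called neither (4681) stayed between 0.957 and 1.03 over these bins. Since neighbours of higher genes were often higher too, gene sides with no other annotated gene within 1.2 kb were also taken alone. Over 1112 such sides of higher genes the ratio was 2.001 (1.88 to 2.13) in the first 100 bp and 1.33 (1.25 to 1.41) at 1 kb, against 1.01 and 0.985 over 3993 sides of genes called neither. Over 413 sides of lower genes the ratio was 0.886 (0.804 to 0.975) and 0.706 (0.629 to 0.791), below the sides of genes called neither. It lay further from 1 away from the gene, unlike in the higher genes, and the cause was not tested. Strand was not used, so both gene ends were averaged.

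**Figure D4:**
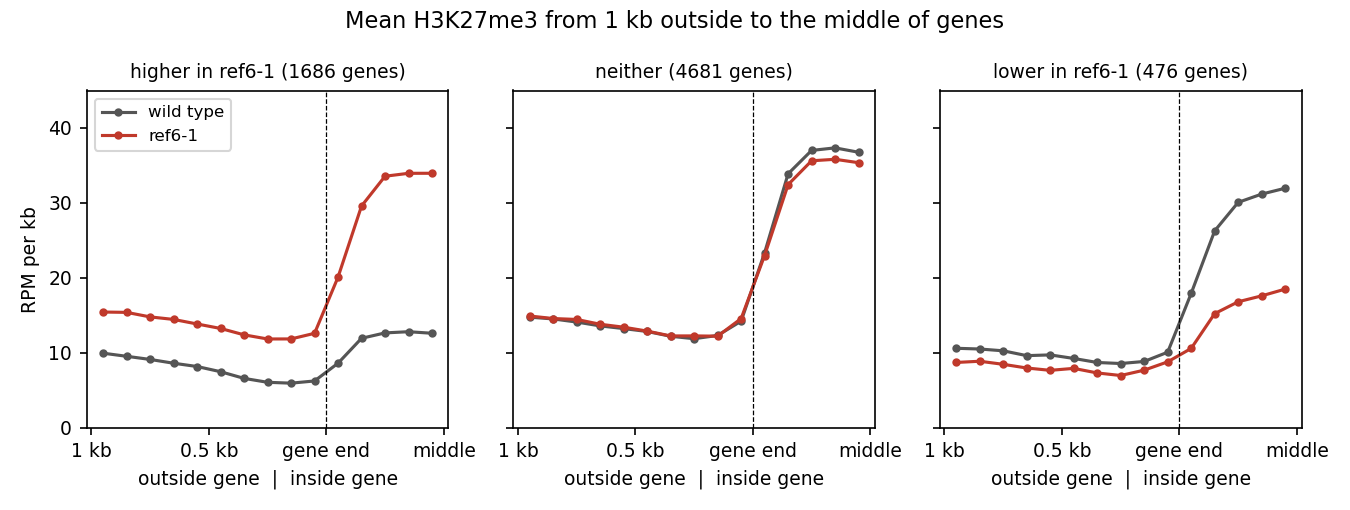
Mean read density in RPM per kb (y axis) from 1 kb outside the gene ends to the middle of the gene (x axis) for higher, neither and lower genes of at least 1 kb, wild type in grey and ref6-1 in red. Inside the genes the curves follow from the calls, and in the 1686 higher genes ref6-1 also lies above wild type up to 1 kb outside.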

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

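The removal of the GC trend, the removal of the trend with wild-type density, the comparison of the gap inside LHP1 with other genes and the tests of the chromosome 2 interval were chosen only after the results were seen. Apart from protein-coding genes, some other genes were also marked, with calls in both directions. Among genes of long noncoding RNA that overlap no protein-coding gene, 72 of 701 marked ones were higher in ref6-1 and 48 were lower. Among 595 marked pseudogenes apart from protein-coding genes, 77 were higher and 37 lower. The median log2 ratio was below 0 in each of these classes, down to −0.06 for pseudogenes not annotated as transcribed. Of the regions higher in ref6-1, 48 overlapped no annotated gene.

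A difference in scaling, or in enrichment that follows density, would give genes of equal wild-type density 1 ratio. With that trend removed, 90.1% of the 1957 genes higher in ref6-1 still passed, beside 90.3% before. After that removal 2640 of 22585 genes passed in all, against at most 383 from counting error alone. That error leaves out variation between libraries. The removed trend was small, from −0.33 to 0.25 on the log2 scale, with a median of −0.05 over 1950 of the higher genes. Of the 1732 genes called higher from plus-strand reads, 99.8% had a ratio above 1 in minus-strand reads, beside 52.5% of all marked genes. Repeats of a position had been removed before this count, and whether copies of 1 fragment stay on 1 strand was not tested. The strand comparison therefore cannot decide whether duplicates of the less complex ref6-1 library contribute. After removal of the GC trend, fitted on unmarked genes, 99.5% of the higher genes kept the call, so that trend does not account for them. A GC effect confined to enriched DNA would not show in that trend and was not tested. A difference between the seedling samples other than genotype cannot be told apart from the genotype with 1 library per genotype, and loss of REF6 activity stays open beside it.

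The wild-type reads over LHP1 lay in 3 blocks between positions 5827794 and 5829536 of chromosome 5 (TAIR9), which held 91.4% of the reads, with a gap from 5828737 to 5829178 that had 1 wild-type and 4 ref6-1 reads. An H3K27me3 domain of the wild type is argued against, since 3 of 1111 other genes of similar wild-type density (0.270%, 0.0557 to 0.787) held a gap as long and under 2 times background, although 1 of these was among only 44 lower genes. DNA without introns, such as a cDNA copy or a construct, may have entered the wild-type library and stays open. Of 5 block edges that could be read, 1 carried splice-site bases, which does not exclude it because edges drawn from coverage are placed only to within about a read.

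On chromosome 2, positions 885952 to 895655 (9.70 kb, TAIR9) held 232 wild-type reads and 0 ref6-1 reads, over AT2G03030 and AT2G03040. Chance at the ref6-1 depth is argued against, since 133.8 reads were expected from the wild-type reads. Loss of H3K27me3 from DNA that is still present would leave background reads, and 37.8 were expected against an upper 95% Poisson bound of 3.69 for a count of 0. DNA absent from the ref6-1 plants may account for the interval. That was not tested apart from these counts, and no biological explanation from the genotype was tested.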

How the results depend on the processing

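The settings with 1 kb beside genes, an alignment score minimum, the GC trend removed, the motif search limits and all list members were chosen only after the results were seen. No paired analysis was possible because each genotype had 1 library. The number of higher genes (1957) stayed within 1.5 times under every alternative except background scaling, which gave 3217 higher and 99 lower genes. Each scaling moves all ratios by 1 factor, upward for background and trimmed-mean scaling, so these could end no higher call, and 1906 remained with the median ratio set to 1. Trimmed-mean scaling gave 342 lower genes, a ratio threshold of 2 gave 172 and gene bodies with 1 kb on both sides 417. The first follows from the shift of all ratios and the second from the stricter threshold, while the cause of the last was not tested. The median log2 ratio of marked genes, 0.026, became 0.43 under background scaling, 0.19 under trimmed-mean scaling and 0 by construction with the median ratio set to 1. It was 0.040 from plus-strand and 0.034 from minus-strand reads, 0.058 for genes marked in either library, 0.00097 for genes marked at 3 times background and 0.0013 for genes with at least 100 reads, and the causes of these small moves were not tested. Over all gene lists, 25 members were higher, and 42 under background scaling. With all members with reads, matched on wild-type density, 2 lists instead of 1 lay above the middle 95% of random lists, because leaf senescence joined. Regions gave 2705 higher and 74 lower under background scaling, 233 lower under trimmed-mean scaling, 136 lower at a ratio of 2, and 2830 and 1268 with all aligned reads kept, where the cause was not tested. The share of reads in regions became 64.8% in wild type and 71.0% in ref6-1 with all reads kept, 48.2% and 52.3% at a Poisson tail under 1e-05, and 57.9% and 63.2% with gaps up to 1000 bp joined, with ref6-1 above wild type each time. The motif difference of 1.14 became 1.22 with all reads kept, 1.06 in genes read over at least 80% of their length (72.9% of marked genes) and 0.93 with copies within 1 kb counted too, and the causes were not tested. Background scaling moves every ratio by 1 factor and says nothing about that difference. Of 39 named genes higher in ref6-1, 28 kept the call under all 19 settings, and of 11 lower ones 3 did. Over 2128 comparisons of named genes, 61 lost and 22 gained a call, and none reversed. The 1 kb upstream of genes and the oriented profile were not run. Depth limits small differences, since the median interval spanned 1.90-fold.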

Other observations

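The family and neighbour comparisons, and the minimum for the motif search with its alternatives, were chosen after seeing the data, while the motif test itself was planned. The families here are groups labelled by a symbol stem, such as CRK, MYB, GA or EDA, and not all of them need be gene families. Among 29 such groups with at least 15 marked members, the cysteine-rich receptor-like kinases (CRK) had the highest median log2 ratio, 1.46, above every one of 10000 random lists matched on density. Of 26 marked CRK genes 23 were higher in ref6-1, 24 lay on chromosome 4 and 23 were next to another CRK gene. Their median density was 2.47 times background in wild type and 7.96 times in ref6-1. CRK19 (7.76-fold, 5.53 to 11.1), CRK20 (6.60, 4.97 to 8.88) and CRK13 (6.31, 4.26 to 9.58) led the family, and of the 3 CRK genes with no CRK neighbour 1 was higher. The random lists drew genes singly and not in runs of neighbours. A place among them therefore takes clustered genes as independent and can overstate how far a group such as CRK stands apart. The ABCG transporters followed with 9 of 17 marked genes higher and a median of 1.03, led by ABCG8 (5.75, 3.84 to 8.82) and ABCG4 (3.99, 2.95 to 5.46). The MYB factors had the lowest place among random lists, with 11 of 92 marked genes higher, 8 lower and a median of −0.15, above 0.27% of the lists, although the medians of the CLE and RALFL families were also −0.15. The MYB median turned to 0.26 under background scaling, with 22 genes higher, and 0.01 under trimmed-mean scaling. MYB61 (10.05, 6.75 to 15.5) and MYB32 (10.02, 4.89 to 23.1) were the most raised, and MYB22 (0.463, 0.267 to 0.766) the most lowered.

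Higher genes lay beside each other more often than random draws of marked genes. Of the 1957 higher genes, 45.5% had a higher gene as a neighbour, against a median of 20.2% and a maximum of 24.1% over 1000 random draws.

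A hypothesis from general knowledge of the zinc fingers of REF6 is that it acts through copies of CTCTGYTY, where Y is C or T. Copies were counted on both strands in the gene bodies of 8784 marked genes with at least 50% of the sequence read, 99.5% of all marked genes and 99.4% of the higher ones. The median log2 ratio was −0.13 with 0 copies (5308 genes), 0.17 with 1 (2062), 0.76 with 2 (816), 1.23 with 3 (350) and 1.73 with 4 or more (248). The share of higher genes over these classes was 7.97%, 27.9%, 56.0%, 76.0% and 90.3%. Genes with at least 2 copies had a median of 1.01, above all 10000 random lists matched on density and length (highest 0.16). The difference from genes with 0 copies, 1.14, was larger than for 99.6% of 1661 other orderings of the same bases, and the 6 orderings as large, such as CYCYGTTT at 1.30, all share a sequence with the motif. The largest ordering that shares none reached 1.09, close to the motif, while the median over the 1661 other orderings was 0.093. Sharing means an identical sequence of 8 bases, so an ordering that overlaps the motif when shifted counts as sharing none. Whether the ordering at 1.09 is unrelated to the motif was not tested, so how far the motif stands apart from unrelated orderings stays open. In genes read over at least 80% the difference was 1.06, as large in 6 of 1602 other orderings, all of them sharing, with 1.01 for the largest that shares none. These values are consistent with the hypothesis, which remains one, since 423 genes with 0 copies were also higher and no binding data were analysed here.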
